A study of Mus musculus with 4 samples.

How the data were processed

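The series holds 4 ChIP-seq libraries made with an antibody against histone H3 propionylated at lysine 23, per the labels. Each library came from a pool of 3 hearts of male C57Bl/6J mice aged 12 weeks. The groups were control diet with sham surgery, control diet with transverse aortic constriction (TAC), a diet free of branched-chain amino acids (BCAA-free) with sham surgery, and the BCAA-free diet with TAC. Diets began 4 days before surgery and hearts were taken 1 week after it. Groups were taken from the treatment labels, and each group had 1 library, so there was no replicate error or SD within a group and no test within a diet or a surgery.

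BWA, MACS2 and the mm10 build are named in the submitters' processing notes, without versions, parameters or the role of each. The authors deposited 1 table in which the peak regions of the 4 libraries were merged into 29210 regions. Per the file headers, each region has for each library an average signal and a peak height, both a signal (density of sequenced fragments), and a 0 or 1 for the presence of a peak call. The scaling between libraries is not given in the sources used here. Region lengths were checked to be whole multiples of 200 bases. The authors also deposited log2 ratios of the average signal and a larger tag number for 4 library pairs, per the file headers. In the authors' deposited table, the log2 ratios equalled the log2 of the quotient of the average signals without a pseudocount, to within 4.44e-16. The tag number in the authors' deposited table equalled the average signal times the region length divided by 224, so the same relation was used to estimate tags for each library. Gene names, gene counts, promoter counts, CpG islands and the distance from the middle of a region to the transcription start were taken from the table. Of 17640 gene names, 15879 were matched in a RefSeq gene table of the mouse assembly GRCm38.p6.

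From the average signal, log2((A + 1)/(B + 1)) was computed for each region and 4 library pairs, with the values as deposited and no filter on low values. This scale understates the ratio of regions of low signal. A region or gene was called higher or lower when the ratio passed 1.5-fold (0.58 on the log2 scale), a rule of size and not a test. Each gene was represented by the listed region nearest to its transcription start, and 8119 genes shared that region with another gene, so a ratio belongs to the region and not to 1 gene of it. The intervals given with single genes are 95% intervals from the estimated tags and cover counting error only. The median number of estimated tags per region was 198 for control sham, 201 for control TAC, 205 for BCAA-free sham and 199 for BCAA-free TAC. The median counting error of a log2 ratio was 0.125 to 0.126 over the 4 comparisons.

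For 21 gene lists (cell type markers, pathways and 2 background lists), the median log2 ratio of the measured members was set among the medians of 10000 random lists of the same size, drawn with replacement from 20 bins of mean signal. A list was said to stand apart when its median lay outside the central 95% of these random medians. Chance would give this for about 5% of lists if their members varied independently. Members that move together within a pool would raise this share, by an amount that is not known here. The percentile describes these libraries and is no test of diet or surgery. An additive model of diet and surgery was also fitted to the log2 values, which gives a t-test of each with 2 pairs and 1 residual degree of freedom. It assumes that the response to TAC is the same on both diets, which is the question of the study. The interval of a list median is a 95% interval from ranks over its members. The lists, the comparisons, the 1.5-fold rule and the rule for named genes were fixed before the data were examined. The 2 further lists and the symbol families of the closing section, the additive model and 4 of the alternative settings were chosen after the data were seen.

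The genes named for a comparison were the 5 with the highest and the 5 with the lowest ratio among 4190 genes whose region had a mean signal above the median of all genes and its middle at most 2500 bases from the start. Predicted genes and small RNAs were left out. To these were added the 2 members with the largest ratio from each list that stood apart, and always Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Postn, Pcca, Pccb and Bcat2. Some genes that this rule selects are left out of the text. Further list members named as examples were chosen after their values were seen.

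The steps were tested on simulated libraries drawn with counting error from the geometric mean of the control-diet sham and TAC signals. These levels were scaled by the library medians, and variation between pools was not simulated. In the simulation of TAC over sham on the control diet, which ran over 29210 regions, 99% of regions raised by 2-fold and 88% of regions lowered to 0.5-fold passed the 1.5-fold rule, as did 0.421% of unchanged regions. Of 21 unchanged lists, 0 stood apart in the simulated comparison on the BCAA-free diet. The alternatives tried were scaling each library to the same median, quantile normalisation, removal of the trend of the ratio with signal (loess after median scaling), a pseudocount of 5 or none, only regions above the median of the mean signal, and peak height in place of the average. Others were a 2-fold rule, only regions called in at least 2 libraries, only autosomes, stricter calls, and other ways to choose the region or genes of a list. The analysis used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.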

Results

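Propionylation of histone H3 at lysine 23 (H3K23) was profiled by ChIP-seq in mouse hearts 1 week after sham surgery or transverse aortic constriction (TAC), a surgical narrowing of the aorta that puts the left ventricle under pressure overload. Mice ate either a control diet or a diet without the branched-chain amino acids leucine, isoleucine and valine (BCAA-free). The catabolism of isoleucine and valine yields propionyl-CoA, the donor of the propionyl group, and the comparisons address whether the BCAA-free diet alters the H3K23 propionylation that goes with pressure overload. There were 4 libraries, 1 per group, each from a pool of 3 hearts, so the differences below have no replicate check. The words higher and lower compare libraries and not conditions. None of the libraries is an input library, and how they were scaled to each other is not given. A change of the same size in all regions could therefore not be told from scaling. The ratios show how regions differ relative to each other, not whether the total level of the mark changed.

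The merged table held 29210 regions with a median length of 6400 bases (400 to 257200), which together covered 299 megabases. A promoter lay in 12520 regions, 10056 held a gene but no promoter, and 6634 held no gene. Peaks were called in 22513 regions for control sham, 23009 for control TAC, 23965 for BCAA-free sham and 22871 for BCAA-free TAC. The same 17894 regions (61.3%) were called in all 4 libraries and 4863 in 1 library. The median average signal was 6.89, 6.95, 7.10 and 6.80 in the same order. With the scaling unknown, these close values do not show whether total propionylation was the same in the groups. The natriuretic peptide genes Nppa and Nppb and the skeletal actin gene Acta1, which cardiomyocytes induce under load, were listed with no region. The nearest regions lay 30.9, 16.0 and 30.0 kb from these genes, so no ratio is given for them.

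On the control diet, regions of macrophage and leukocyte genes had a higher H3K23 propionylation signal in the TAC library than in the sham library, and regions of contractile, calcium handling and fatty acid oxidation genes had a lower one. The leukocyte list had a median log2 ratio of 0.60 (interval 0.33 to 0.70). Of its 23 measured members, 13 were at least 1.5-fold higher and 0 were 1.5-fold lower. The sarcomere list had a median of −0.34 (−0.75 to −0.23), with 0 members higher and 9 of 23 lower past 1.5-fold. Calcium handling and ion channel genes had a median of −0.40 (−0.51 to −0.12) with 3 of 22 members lower, and fatty acid oxidation genes −0.32 (−0.47 to −0.14) with 4 of 28 lower.

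Among leukocyte genes, Fcgr1, which encodes an Fc receptor of macrophages, had an average signal of 9.25 in TAC against 3.70 in sham, a log2 ratio of 1.13 (counting interval 0.81 to 1.44). Csf3r, the receptor for granulocyte colony-stimulating factor, had a ratio of 0.98. Genes were also ranked among the 4190 whose region lies at the start and has a mean signal above the median of all genes. The highest of these was Tnfaip8l2, a regulator of immune signalling, with 1.12 (0.88 to 1.35) in a region of 4600 bases on chromosome 3 (95139400 to 95143999) that also lists Scnm1 and Lysmd1. Arhgap22 had 0.98, the C-type lectin gene Clec4a3 0.95, the immune receptor adaptor gene Hcst 0.89 in a region that also lists Tyrobp, Nfkbid and Aplp1, and Ly86 0.86.

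The lowest ratios of this ranking belonged to Ttn, which encodes the giant sarcomere protein titin, at −0.92 (−1.13 to −0.71), and to cardiac actin Actc1 at −0.89 (−1.04 to −0.74). The Ttn region (chromosome 2, 76979600 to 76985999) had a signal of 7.70 in TAC against 15.4 in sham. Ckmt2, a mitochondrial creatine kinase, had −0.87, Chrna2 −0.82 in a region shared with Ptk2b, and the desmosomal cadherin gene Dsg2 −0.80. The region at the start of the alpha myosin heavy chain gene Myh6 (chromosome 14, 54955600 to 54976999), which also lists Myh7, had −0.78 (−0.89 to −0.66). The nearest region to the start of the beta isoform gene Myh7 had −0.58. Ratios were −0.68 for the ryanodine receptor gene Ryr2 and −0.37 for the calcium pump gene Atp2a2. In fatty acid oxidation, the fatty acid binding protein gene Fabp3 had −0.80 and the lipid-sensing nuclear receptor gene Ppara −0.74.

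Mitochondrial lists lay lower as well. Oxidative phosphorylation genes had a median of −0.19 (−0.21 to −0.09) with 2 of 41 members lower past 1.5-fold. Cox6a2 had −0.76 in a region that also lists Itgad and 4931431B13Rik. Ndufb5 had −0.69 in a region downstream, with its middle 16736 bases from the start. The tricarboxylic acid cycle list had −0.15 (−0.34 to −0.05, 0 of 22 members past 1.5-fold), with Idh3a at −0.43. BCAA catabolism genes had −0.09 (−0.24 to 0.07), with 1 of 24 members lower past 1.5-fold. This was Bckdhb, a subunit of the branched-chain ketoacid dehydrogenase, at −0.64, followed by Acat1 at −0.38, and the mitochondrial transaminase gene Bcat2 had −0.30. Propionyl-CoA metabolism genes had −0.08 (−0.19 to 0.08) with 0 of 22 members past 1.5-fold. Sucla2 had −0.41, Acss1 −0.37, and the 2 propionyl-CoA carboxylase genes Pcca and Pccb −0.06 each.

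Extracellular matrix genes had a higher signal in TAC, with a median of 0.24 (0.17 to 0.30) and 32 of 39 members above the median of all genes. The matrix protein gene Postn, which activated fibroblasts secrete, had 0.65 (0.41 to 0.89) and was the 1 member past 1.5-fold. Tnc had 0.51 and Col1a1 0.35. Fibroblast markers had a median of 0.17 (0.12 to 0.27), with S100a4 at 0.38 and Tcf21 at 0.35, and share 6 genes with the matrix list. Cell cycle genes had 0.29 (0.12 to 0.51), with 4 of 27 members higher past 1.5-fold, Ccna2 at 0.78 and Tpx2 at 0.76 among them. Endothelial markers had a lower median of −0.22 (−0.29 to −0.11), with Sox17 at −0.40 and Ly6c1 at −0.39.

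These 12 lists stood apart from random lists, 4 higher and 8 lower. The lists of fetal and hypertrophy genes (0.01), immediate early and stress genes (0.06), histone acylation enzymes (0.03), glycolysis (0.06), smooth muscle and pericyte markers (0.01), ribosomal proteins (0.06) and the amino acid starvation response (0.02) did not, in this or the other comparisons, and neither did the background lists of skeletal muscle (0.06) and liver and neuron genes (−0.04). With only genes alone in their region, the BCAA catabolism (percentile 7.42), propionyl-CoA (9.14), oxidative phosphorylation (7.88), tricarboxylic acid cycle (2.83) and fibroblast (92.7) lists no longer stood apart, and the propionyl-CoA and fibroblast lists also lost their place with peak height (7.71 and 81.8) and without genes of another list (4.07 and 83.1). Medians with genes alone in their region were −0.09 (BCAA catabolism), −0.06 (propionyl-CoA), −0.12 (oxidative phosphorylation), −0.20 (tricarboxylic acid cycle) and 0.18 (fibroblast). With the region of highest signal per gene, the cell cycle (92.5) and BCAA catabolism (3.35) lists did not stand apart, and Fcgr1, Csf3r, Tpx2 and Bckdhb had ratios of −0.07, −0.17, −0.18 and 0.14.

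**Figure D1:**
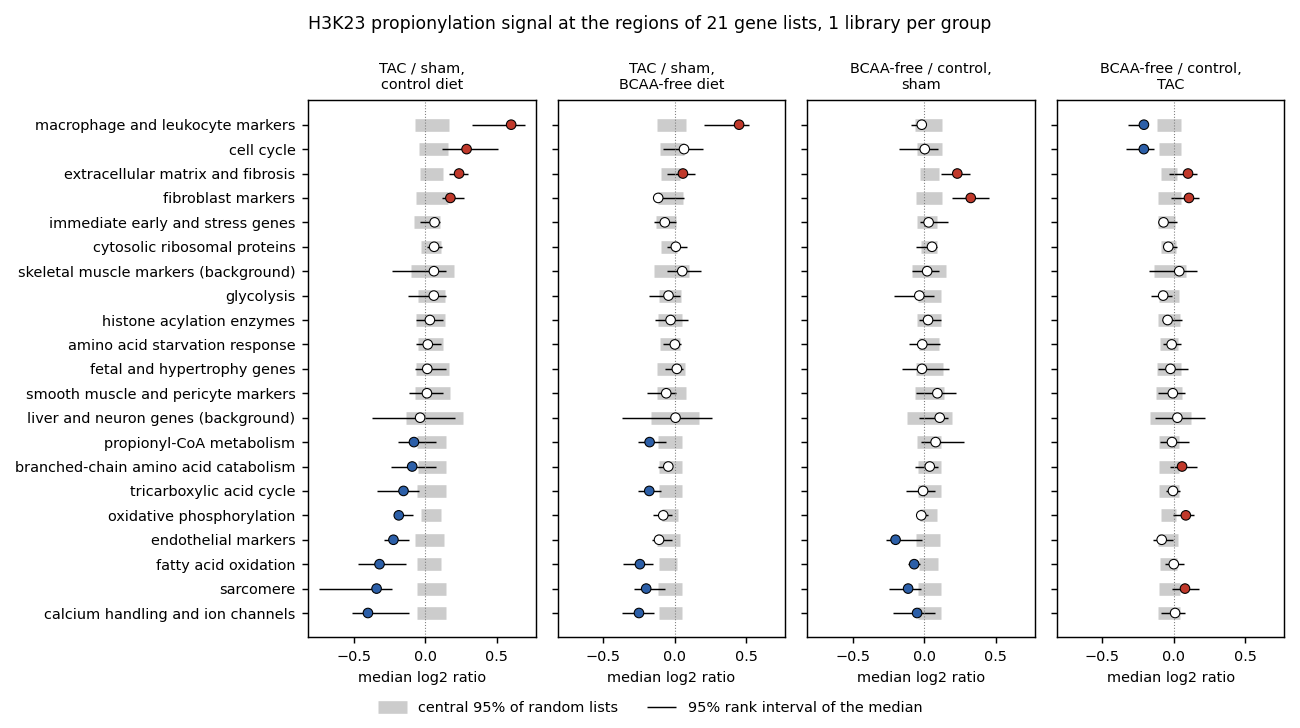
Median log2 ratio of H3K23 propionylation signal (horizontal axis) for 21 gene lists in the 4 comparisons, 1 library per group. Points are list medians (red, above the central 95% of random lists; blue, below it; white, within it), black lines are 95% rank intervals of the median, and grey bars span the central 95% of random lists. Macrophage and leukocyte markers reach 0.60 and 0.45 in the TAC comparisons, and sarcomere genes lie at −0.34 and −0.20.

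Over all regions on the control diet, 1275 were higher and 1551 lower in TAC past 1.5-fold, and the median of all regions was 0.04. Regions with a promoter were more often higher (406) than lower (207), while regions with a gene but no promoter were more often lower (800) than higher (441). With the trend of the ratio with signal removed, the counts were 993 higher and 1881 lower. Counting error alone, simulated at these depths, put 113 regions past 1.5-fold.

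On the BCAA-free diet, leukocyte genes were again higher in the TAC library and contractile, calcium handling and fatty acid oxidation genes lower. The leukocyte list had a median of 0.45 (0.21 to 0.52), and 22 of 23 members lay above the median of all genes, although 1 member, Fcgr1 at 0.64, passed 1.5-fold. Laptm5, a lysosomal membrane protein gene of blood cells, had 0.56 (0.45 to 0.67). Sarcomere genes had a median of −0.20 (−0.28 to −0.07) with 0 of 23 members past 1.5-fold, and Actc1 at −0.55 and Actn2 at −0.49 were the lowest. Calcium handling genes had −0.25 (−0.37 to −0.14), with Jph2 and Cacna1c at −0.53 each and Atp2a2 at −0.33.

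Fatty acid oxidation genes had a median of −0.24 (−0.36 to −0.15). The 2 of 28 members lower past 1.5-fold were Decr1 at −0.60 and the fatty acid transporter gene Cd36 at −0.59, whose region had a signal of 10.5 in TAC against 16.4 in sham. The tricarboxylic acid cycle list had −0.18 (−0.26 to −0.09), with Sdhc at −0.38 and Idh2 at −0.30. The middle of the Idh2 region lay upstream, at −20549 bases from the start. Propionyl-CoA metabolism genes had −0.18 (−0.26 to −0.06), with Acsf3 at −0.45, Mmachc at −0.35, Pcca at −0.24 and Pccb at −0.14, and 0 of 22 members passed 1.5-fold. BCAA catabolism genes had −0.05, within the range of random lists. Of the myosin genes, Myh6 had −0.16 and Myh7 −0.24.

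Matrix genes had a median of 0.06 (−0.06 to 0.14) with 2 of 39 members higher past 1.5-fold, namely Tnc at 0.75 and Cthrc1 at 0.68. Postn had 0.37 and Col1a1 0.28. Fibroblast (−0.12), endothelial (−0.11) and cell cycle (0.06) markers did not stand apart. The highest ratios of the same ranking of genes were Arhgap22 at 0.83 (0.61 to 1.04), Iqgap2 at 0.76, the homeobox gene Hhex at 0.76, the macrophage gene Aif1 at 0.74 in a region that also lists Lst1 and Prrc2a, and Rnf180 at 0.66. The lowest were Ccdc83 at −0.76 (−1.29 to −0.23) and Chrna2 at −0.61, followed by Cd36, the pseudogene Trmt112-ps2 at −0.57 and Otop2 at −0.55.

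In this comparison 413 regions were higher and 693 lower past 1.5-fold, with a median of all regions of −0.06. With each library scaled to the same median, 599 were higher and 472 lower, so which direction prevailed depended on the scaling. The 2 lists that stood apart higher were the leukocyte and matrix lists, and 5 stood apart lower. With peak height the calcium handling (percentile 10.98), propionyl-CoA (20.1), fatty acid oxidation (20.8), tricarboxylic acid cycle (7.43) and matrix (88.6) lists no longer did. The matrix list also lost its place with regions above the median signal (89.5), genes alone in their region (90.2) and genes of no other list (96.9), the calcium handling list with regions near the start (3.55) and the tricarboxylic acid cycle list with genes alone in their region (2.86). The tricarboxylic acid cycle list had medians of −0.20 with genes alone in their region and −0.13 with peak height. With the region of highest signal per gene, Fcgr1, Iqgap2 and Aif1 had −0.07, −0.20 and −0.18.

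Set side by side, the TAC ratios of the 2 diets, which share no library, went together across regions (Pearson r = 0.53, Spearman rho = 0.51 over 29210 regions, which are not independent replicates). Of the regions past 1.5-fold on the control diet, 182 were also higher and 252 also lower on the BCAA-free diet, against 18.0 and 36.8 for independent lists, and 11 went in opposite directions between the diets. The 1275 regions that were higher on the control diet had a median of 0.32 on the BCAA-free diet, and the 1551 lower ones −0.35. More regions passed 1.5-fold on the control diet (2826) than on the BCAA-free diet (1106). The TAC ratio on the BCAA-free diet minus that on the control diet had a median of 0.18 (0.06 to 0.34) for sarcomere genes (percentile 100). Above random lists but with intervals that include 0 lay calcium handling (0.12), oxidative phosphorylation (0.04), BCAA catabolism (0.06), fatty acid oxidation (0.03) and endothelial genes (0.05, percentile 99.2), against −0.07 for all genes. Titin was at −0.92 on the control and −0.33 on the BCAA-free diet, and Myh6 at −0.78 and −0.16. The difference was −0.20 (−0.41 to −0.08) for fibroblast markers (percentile 0.38). For the leukocyte list it was −0.16 (3.33), which did not stand apart, whereas a second list of 32 leukocyte genes, chosen after the data were seen, had −0.23 (−0.31 to −0.18, percentile 0.01) and did. Peak height ended the call of the BCAA catabolism (percentile 86.7), fatty acid oxidation (81.9, median −0.03), fibroblast (22.8) and endothelial (96.9) lists, genes alone in their region that of the BCAA catabolism (94.0), oxidative phosphorylation (79.9) and endothelial (95.03) lists, regions near the start that of the calcium handling (84.0) and fibroblast (7.06) lists, and regions above the median signal that of the fibroblast list (4.05). With 1 library per group, none of these differences between diets could be tested.

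**Figure D2:**
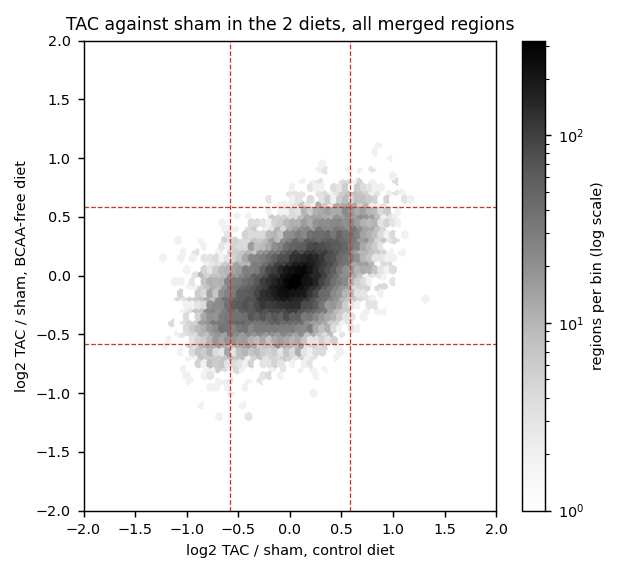
Log2 ratio of TAC over sham on the control diet (horizontal axis) against that on the BCAA-free diet (vertical axis) for all merged regions. Shading is the number of regions per hexagon on a log scale and dashed red lines mark 1.5-fold, past which 182 regions were higher and 252 lower in both diets.

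In sham-operated hearts, fibroblast and matrix genes had a higher signal on the BCAA-free than on the control diet, and endothelial and sarcomere genes a lower one. Fibroblast markers had a median of 0.32 (0.19 to 0.45) with 4 of 20 members higher past 1.5-fold, and the matrix list 0.23 (0.12 to 0.32) with 2 of 39. Dcn, which encodes the collagen-binding proteoglycan decorin and is in both lists, had a signal of 14.0 against 8.45, a ratio of 0.66 (0.56 to 0.77). The dermatopontin gene Dpt had 0.73 (0.23 to 1.22), the fibroblast transcription factor gene Tcf21 0.62 and the lumican gene Lum 0.59. Postn had 0.23 and Col1a1 0.17. Endothelial markers had a median of −0.20 (−0.27 to −0.02), with Sox17 at −0.39 and the endothelial cadherin gene Cdh5 at −0.36, and 0 of 20 members past 1.5-fold.

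Sarcomere genes had a median of −0.11 (−0.25 to −0.02) on the BCAA-free diet in sham, with Tcap at −0.45 and Myh6 at −0.44. Fatty acid oxidation genes had −0.07 (−0.11 to −0.03), with Fabp3 at −0.30 and Ppara at −0.28, and calcium handling genes −0.05 (−0.22 to 0.08), with Kcnh2 at −0.41. In these 3 lists 0 members passed 1.5-fold. The leukocyte list had −0.02 and did not stand apart. BCAA catabolism genes (0.04), propionyl-CoA metabolism genes (0.08) and the amino acid starvation response (−0.01) lay within the range of random lists. Bcat2 had −0.02, Pcca 0.00, Pccb 0.08 and Atp2a2 −0.03.

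In the ranking of genes at their start, the highest ratios in sham were Ccdc83 at 0.70, the DNA repair gene Smug1 at 0.69, Chm at 0.68, Dhx35 at 0.68 and Dynlt1f at 0.67. The Ccdc83 region had a signal of 14.4 (64.0 estimated tags) in BCAA-free sham and of 8.07 to 9.97 in the other libraries. Its low TAC ratio on the BCAA-free diet rests on the same BCAA-free sham value. The lowest were the cardiolipin synthesis gene Tamm41 at −0.60 (−1.04 to −0.15), Ckmt2 at −0.58, Sec1 at −0.53, the interferon-induced gene Oas2 at −0.52 and Nr0b2 at −0.48. In all, 791 regions were higher and 400 lower past 1.5-fold. In TAC-operated hearts, 75.6% of the higher ones lay above the median diet ratio of all regions, and 65.0% of the lower ones below it.

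The split in sham depended on the scaling, with 606 higher and 498 lower after scaling to the same median, 501 and 530 after quantile normalisation and 522 and 576 after removal of the trend. The fibroblast, matrix and endothelial lists stood apart under all 11 alternatives run for the lists, whereas peak height ended the call of the sarcomere (percentile 11.7), fatty acid oxidation (18.1, median 0.01) and calcium handling (12.6) lists, genes alone in their region that of the sarcomere list (4.17), and 5 more alternatives that of the calcium handling list (2.54 to 45.5, median 0.05 with regions near the start).

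In TAC-operated hearts, leukocyte and cell cycle genes had a lower signal on the BCAA-free than on the control diet, while matrix, fibroblast, oxidative phosphorylation, sarcomere and BCAA catabolism genes lay above random lists with medians whose intervals include 0. The leukocyte list had a median of −0.21 (−0.32 to −0.18). Emr1, which encodes the macrophage surface protein F4/80, had a signal of 5.59 on the BCAA-free against 10.5 on the control diet, a ratio of −0.80 (−1.11 to −0.49), and was the 1 of 23 members past 1.5-fold. The T cell receptor subunit gene Cd3d had −0.57 in a region shared with Cd3g. Cell cycle genes had a median of −0.21 (−0.33 to −0.14) with 3 of 27 members lower past 1.5-fold. The mitotic spindle gene Tpx2 had −0.88 (−1.22 to −0.54), the cyclin gene Ccna2 −0.76 in a region shared with Exosc9 and Bbs7, and Ccnb2 −0.62.

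These 5 lists held no member past 1.5-fold. Matrix genes had a median of 0.10 (−0.03 to 0.16), with Timp1 at 0.46 and Mmp2 at 0.37, and fibroblast markers 0.11 (−0.02 to 0.18), with Dcn at 0.33 and Fbln1 at 0.30. Oxidative phosphorylation genes had 0.08 (−0.01 to 0.14), with Cox7b at 0.34 and Cox5b at 0.30, and 31 of 41 members above the median of all genes. Sarcomere genes had 0.08 (−0.02 to 0.18), with Ttn at 0.34 and Myh6 at 0.18. The list member Myl9 had 0.31, but unlike the list it was also higher on the BCAA-free diet in sham (signal 8.23 against 6.13). BCAA catabolism genes had 0.06 (−0.02 to 0.16), with Mccc1, a subunit of the leucine-pathway carboxylase, at 0.51, the isovaleryl-CoA dehydrogenase gene Ivd at 0.34 and Bcat2 at 0.23. Propionyl-CoA metabolism genes had −0.01, within the range of random lists, with Pcca at −0.17 and Pccb at 0.00. Atp2a2 had 0.01, Col1a1 0.10 and Postn −0.05.

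In the same ranking for TAC, the highest ratios were the RNA methyltransferase gene Ftsj1 at 0.87 (0.48 to 1.26), Magohb at 0.59, Evc and Evc2, which share 1 region, at 0.58, and Chm at 0.58. Chm had also been among the highest in sham. The lowest were Mcts1 at −0.64, Cdkl4 at −0.60, the replication gene Dscc1 at −0.58 and Prps2 at −0.53. A region of 400 bases listed under Lipo1 had −0.94 (−1.77 to −0.11), but the gene table places Lipo1 elsewhere on chromosome 19, so this ratio is not assigned to the gene.

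This comparison had the fewest regions past 1.5-fold, 277 higher and 281 lower (343 and 232 with each library scaled to the same median). Genes alone in their region ended the call of the leukocyte (percentile 4.37), sarcomere (97.4), BCAA catabolism (91.1) and oxidative phosphorylation (84.3) lists, peak height that of the sarcomere (96.1) and BCAA catabolism (91.2) lists, quantile normalisation that of the BCAA catabolism list (97.2), regions near the start that of the fibroblast list (95.8), and removal of genes of another list that of the matrix (93.9) and fibroblast (90.2) lists. Medians with genes alone in their region were −0.18 for leukocyte, 0.14 for sarcomere, 0.08 for BCAA catabolism and 0.04 for oxidative phosphorylation genes. Without genes of another list they were 0.02 for matrix and 0.04 for fibroblast genes. The diet ratios of the 2 surgeries correlated across regions with r = 0.27, with 52 regions higher and 25 lower in both, against 7.50 and 3.85 for independent lists.

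**Figure D3:**
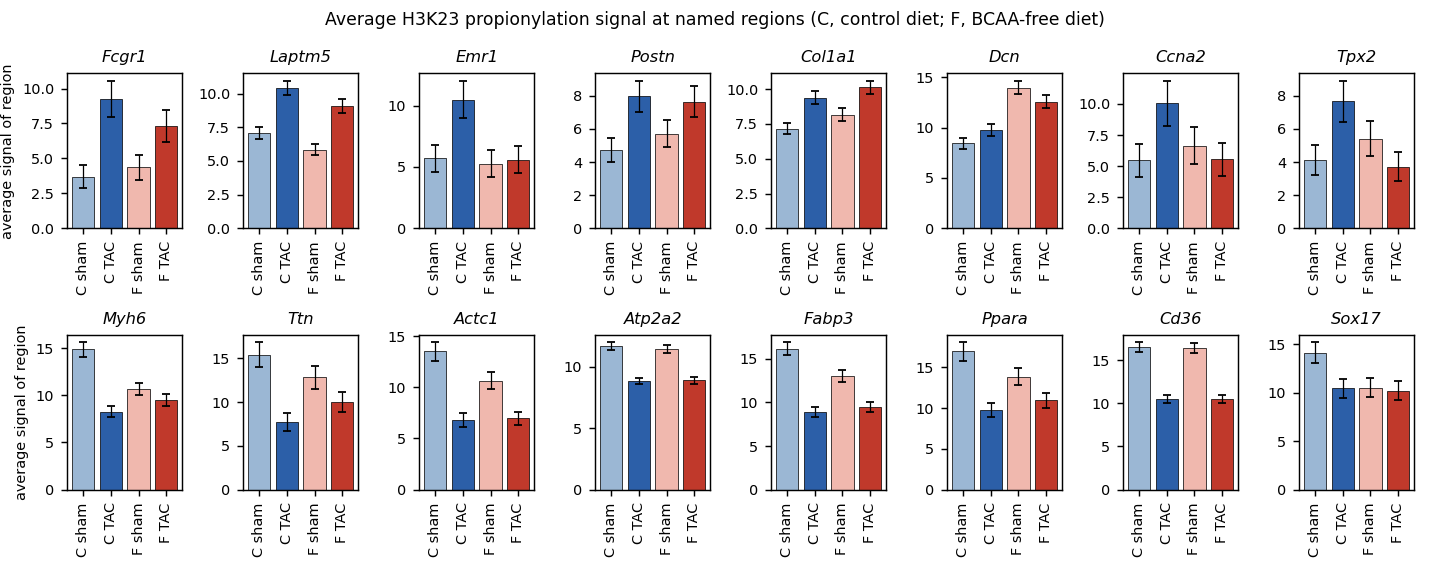
Average H3K23 propionylation signal (vertical axes, starting at 0) in the 4 libraries (C, control diet; F, BCAA-free diet) at the region nearest the start of 16 genes. Bars are single libraries and error lines are 95% counting intervals, not replicate errors. Fcgr1 stands at 3.70 in control sham and 9.25 in control TAC, and Ttn at 15.4 and 7.70.

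The diet comparison in sham shares the control sham library with the TAC comparison on the control diet, and the diet comparison in TAC shares its TAC library. In the same way, the 2 diet comparisons share the BCAA-free sham and BCAA-free TAC libraries with the TAC comparison on the BCAA-free diet. The values of these comparisons are therefore not independent of each other. As library pairs, control TAC and control sham differed most (2826 regions past 1.5-fold) and the TAC libraries of the 2 diets least (558). BCAA-free sham against control TAC gave 2573 and BCAA-free TAC against control sham 2261.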

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

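The test weighed here was chosen after the result was seen.

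Sarcomere genes stood apart in opposite directions between the surgeries. The BCAA-free over control diet ratio had a median of −0.11 in sham and of 0.0774 in TAC over the same 23 members, a difference that was not tested because each group has 1 library. In TAC the list lay at percentile 99.7. It lay within the range of random lists with peak height (96.1, median 0.12) and with genes alone in their region (97.4, median 0.14). In sham it also lay within the range with these alternatives (percentiles 11.7 and 4.17, medians −0.02 and −0.11). A lower leukocyte share in the BCAA-free TAC pool would raise sarcomere, endothelial and fibroblast genes alike in TAC. The sarcomere median exceeded the endothelial median by 0.16 (bootstrap interval over list members 0.04 to 0.26), but lay with the fibroblast median (difference −0.03, −0.14 to 0.10). The bootstrap holds no variation between pools. Endothelial genes were not raised (median −0.09, interval −0.15 to −0.01, percentile 9.2), which argues against this explanation alone for them. For sarcomere and fibroblast genes the explanation stays open. Both directions were kept under the 3 other scalings. The random lists come from the same rescaled ratios and are matched on signal, so scaling could hardly change the place of the list. This result therefore cannot decide whether the scaling plays a part. A difference between single pools that has nothing to do with diet stays open, as does a diet effect that depends on surgery, which was not tested.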

How the results depend on the processing

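Each group has 1 library, so no library could be left out of a comparison. In an additive model of diet and surgery, chosen after the data were seen (t-test over 2 pairs, 1 residual degree of freedom that also holds any interaction), 0 of 29210 regions passed a Benjamini-Hochberg adjusted p of 0.05 for TAC (smallest 0.566) or for diet (0.776). The same held for 0 of 21 lists (smallest adjusted p 0.451 and 0.386). With 1 residual degree of freedom the t-test has little power after adjustment, so it does not show that nothing differed. Values are given in the order TAC over sham on the control diet, TAC over sham on the BCAA-free diet, BCAA-free over control diet in sham and BCAA-free over control diet in TAC, where 4 are given. Besides the results below, 134 of 237 leading results were labelled the same under the alternatives. So were 897 of 1012 values of named genes and 1061 of 1120 list medians. This label is loose and allows a change in size. With each library scaled to the same median, it covers 599 regions higher and 472 lower for TAC on the BCAA-free diet. The main counts there were 413 and 693, so the label does not show that the prevailing direction was kept. Of 84 median log2 ratios by position class, 14 stayed the same and 70 moved. Of 39 calls of a list in a comparison, out of 21 lists, 13 were kept under all 11 alternatives for lists. Where no reason is given, the cause was not tested.

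The median shift of all regions was 0.0256, −0.0023, 0.0067 and 0.0017 with each library scaled to the same median, 0.0231, −0.0002, 0.0009 and −0.0011 with quantile normalisation, and 0.0074, 0.0003, 0.0001 and −0.0006 with the trend with signal removed. In the diet comparison in sham, 501 regions were higher with quantile normalisation and 522 with the trend removed. The Pearson r of the diet ratio in the 2 surgeries was 0.279 with quantile normalisation and 0.282 with the trend removed.

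A pseudocount of 5 pulls every ratio towards 0. The counts past 1.5-fold were 128 higher and 205 lower, 30 and 53, 59 and 41, and 16 and 20, with median shifts of 0.0246, −0.0379, 0.0299 and −0.0169. With no pseudocount, which was chosen after the data were seen, 2014 regions were higher in TAC on the control diet, 798 were higher and 1187 lower on the BCAA-free diet, 1400 and 697 in the diet comparison in sham and 538 and 551 in that in TAC. The median shifts were then 0.0423, −0.0634, 0.0510 and −0.0286.

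With only regions above the median signal there were fewer regions to count. The counts were 275 higher and 587 lower, 71 and 196, 184 and 90, and 56 and 50. The median shift was 0.0258 on the control diet, 0.0343 for diet in sham and −0.0293 for diet in TAC. Across regions, r was 0.57 for the TAC ratio in the 2 diets and 0.29 for the diet ratio in the 2 surgeries.

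With peak height, which rests on fewer tags than the average, the counts were 3021 higher and 3025 lower, 1550 and 2649, 2689 and 1319, and 1422 and 1401. The median shifts were 0.0330, −0.0721, 0.0780 and 0.00, and r was 0.39 for the TAC ratio and 0.15 for the diet ratio. The fatty acid oxidation list turned from below 0 to 0.0128 for diet in sham, and from above 0 to −0.0258 for the TAC ratio on the BCAA-free minus that on the control diet.

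A 2-fold rule leaves fewer regions by construction: 73 higher and 97 lower, 23 and 35, 39 and 24, and 10 and 10. Among regions called in at least 2 libraries, 744 were higher in TAC on the control diet, 223 higher and 369 lower on the BCAA-free diet, 379 and 125 in the diet comparison in sham and 120 and 73 in that in TAC. With calls limited to a peak height above the median of the library, the regions called were 14260 for control sham, 14349 for control TAC, 14036 for BCAA-free sham and 14219 for BCAA-free TAC.

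With the region of highest signal per gene, a different region stands for some genes. The TAC over sham ratio on the control diet turned to 0.14 for Bckdhb, −0.0652 for Fcgr1, −0.17 for Csf3r and −0.18 for Tpx2. On the BCAA-free diet it turned to −0.20 for Iqgap2, −0.18 for Aif1 and −0.0687 for Fcgr1. With regions near the start, the calcium handling list had 0.0463 for diet in sham.

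For the TAC ratio on the BCAA-free minus that on the control diet, the number of lists standing apart lower was 2 with quantile normalisation, 2 with the trend removed, 4 with a pseudocount of 5, 0 with regions above the median signal, 2 with the region of highest signal per gene, 0 with regions near the start, 3 with genes alone in their region and 2 without genes of another list. The number apart higher was 3 with peak height. For TAC over sham on the BCAA-free diet, the number apart higher was 1 with regions above the median signal, 1 with peak height and 1 without genes of another list, and the number apart lower was 3 with peak height. For diet in sham, 2 lists were apart lower with peak height. With genes alone in their region, 4 lists were apart lower for TAC over sham on the control diet, and 2 were apart higher and 1 lower for diet in TAC. Without genes of another list, 3 were apart higher for diet in TAC.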

Other observations

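Of the tests in this part, those of the cardiomyocyte share and of the interferon list by surgery were chosen after the result was seen, and the symbol families and the 2 further gene lists were chosen after the gene lists had been examined. Genes were also grouped by the letters their symbols start with, which gave 166 families of at least 10 genes in at least 8 regions. The families named here lay in the outermost 0.1% of random lists. Chance would place 0.166 per comparison there if genes varied independently, and more if genes of a family move together within a pool. Genes that share a region make this range too narrow, so each family was also tested with 1 gene per region. In TAC over sham on the control diet, 8 families lay there and 7 of them still did with 1 gene per region. Toll-like receptor genes (Tlr, 11 genes) had a median log2 ratio of 0.52 with 5 higher past 1.5-fold, C-type lectin genes (Clec, 23) 0.47 with 9 higher and chemokine genes (Ccl, 18) 0.44 with 5 higher. Canonical histone genes (Hist, 55 genes in 20 regions) had 0.33, and 0.30 (0.11 to 0.41) with 1 gene per region, although these genes have near-identical copies between which reads may be shared (a median of 0.31 with the trend of signal removed). Lower families were Asb (16) at −0.27, inward rectifier potassium channel genes (Kcnj, 14) at −0.23 and Cox (25) at −0.14, with intervals that include 0. TNF receptor family genes (Tnfrsf, 16) had 0.35, but 0.23 (percentile 99.5) with 1 gene per region. On the BCAA-free diet Tlr genes had 0.44, while Hist (0.13, percentile 99.86 with 1 gene per region) left the outermost range. The 16 Asb genes (−0.20) lie in 16 regions, so their percentiles of 0.04 and 0.10 differ only through the random lists.

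In the diet comparison in sham, collagen genes (Col, 39) had a median of 0.21 and zinc finger genes (Zfp, 319) 0.08, and Hist genes (0.16) lay at percentile 99.8 with 1 gene per region. In TAC, Clec genes had −0.24 (−0.37 to 0.06) and Zfp genes 0.02, and Cyp genes (35) had 0.10, but 0.0416 (−0.05 to 0.19, percentile 98.3) with 1 gene per region. The TAC ratio on the BCAA-free minus that on the control diet was −0.42 for Ccl genes, −0.25 for nucleoporin genes (Nup, 22) and −0.21 for sorting nexin genes (Snx, 30). For Hist genes it was −0.17, at percentile 2.63 with 1 gene per region, within the range of random lists. All of these families kept their direction under the 3 other scalings. The 5 regions on chromosome Y, at Ddx3y, Uty, Eif2s3y, Kdm5d and Uba1y, had BCAA-free over control ratios of 0.11, 0.36, 0.47, 0.51 and 0.48 in TAC, although all pools were male.

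In both diets the leukocyte list was higher and the sarcomere list lower in TAC. A trend of the ratio with signal does not account for it, since the control-diet leukocyte median was 0.55 after removal of the trend and still stood apart. A lower share of cardiomyocyte chromatin alone would raise every other cell type alike, but on the control diet the endothelial median lay below the leukocyte median (a difference of −0.82), and their intervals did not overlap. More leukocyte chromatin in the TAC pools would raise nearly all leukocyte genes: of a second list of 32 measured leukocyte genes, 29 on the control and 28 on the BCAA-free diet (87.5%) lay above the median of all genes, just short of the 90% set in advance on the latter. More leukocytes and more propionylation within leukocytes cannot be told apart here, because a pooled heart gives 1 signal over all cells.

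Fewer regions passed 1.5-fold between TAC and sham on the BCAA-free diet (1106) than on the control diet (2826). Counting error of shallow regions does not account for it, since in 2302 regions of at least 1000 tags the spread of the ratio was still 1.43 times larger on the control diet, with 12 regions higher and 36 lower past 1.5-fold against 0 and 7. A smaller response to TAC on the BCAA-free diet is a candidate explanation, as is an unusual pool in 1 or both control groups, and with 1 pool per group neither was tested.

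Oas2, an interferon-induced antiviral gene, had lower BCAA-free over control ratios in both surgeries, which raised the hypothesis that interferon-stimulated genes might be lower together on this diet. A list of 29 other measured interferon-stimulated genes lay at percentile 64.0 in sham (median 0.04, and −0.01 after quantile normalisation), which speaks against the hypothesis there. In TAC it lay at percentile 0.48 (median −0.12) as the hypothesis has it, and the leukocyte list was lower in the same comparison (−0.21).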
